A study of Mus musculus with 4 samples.

How the data were processed

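Whole hearts of C57BL/6 mice were used for ChIP-seq of TFIIB in 3 groups of 1 library each, normal adult, adult after TAC and neonate, with 1 library of input DNA. Per the labels' protocols, a service company carried out chromatin immunoprecipitation, library construction and Illumina sequencing, and the submitters' processing notes name the mouse genome build mm9. The aligner, the interval caller, its thresholds, the scaling to depth and the use of the input library are not given in the sources used here.

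The deposited data are 2 tables, 1 of regions and 1 of genes. Per the file headers, the region table gives the position and length in bp of each merged region, the numbers of called intervals, CpG islands, promoters and genes in it, and the names, distances and relative positions of its genes. The gene table gives each gene's position, length and numbers of regions and intervals, and a peak value. This peak value is a signal that the authors deposited as a whole number, the highest in any library over the regions assigned to the gene, with no statement of its unit or normalization. It is a maximum over libraries and regions, so the number of regions of a gene can affect it, and any difference in depth between libraries may enter it. The tables were checked for what they hold. Region length equalled end minus start in 100% of regions, distances equalled region centre minus gene start within 1 bp in 99.99% of pairs, and 99.99% of pairs had a gap of at most 10 kb between region and gene. The 1264 regions named by 2 or more genes with no other region carried 1 value each.

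The tables name ChIP libraries by 3 codes that match no sample label. The 15 columns of per-library values and presence were therefore not used in any step, nor were the library names beside peaks and intervals, and no library was assigned to a group from its values or order. Those columns were looked at when the tables were opened, before this was decided. The comparisons designed before the data were examined (TAC with adult, neonate with adult, neonate with TAC, their overlap, regions per library and list medians of log2 ratios) were therefore not run. The naming rule fixed with them rested on fold changes. What remained of it was the 7 genes named in advance (Nppa, Nppb, Myh6, Myh7, Acta1, Ankrd1, Gtf2b). The other named genes were chosen after their values were seen. They are those with the highest peak values of all genes, those with the highest among genes with 1 region, centred within 1000 bp of the start, and members of the gene lists. A few genes that these rules would name are not reported here. The location of regions and its 500 and 5000 bp settings, the 34 gene lists and the use of 10000 random lists were fixed before the data were examined; every other analysis was chosen after the structure of the tables was seen.

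A region was called a start-site region of a gene when its centre lay within 1000 bp of the gene's start. A gene's symbol is the one in the table, with the current symbol added in places. Of the gene IDs, 13659 matched the RefSeq gene table of assembly GRCm38.p6, and 10244 of them had the same symbol. That table was used for names and for the list of protein-coding genes only. The lists held 932 entries, of which 1 was not matched. Coverage of a list was the share of its protein-coding members with a start-site region, compared with the other of 18403 named protein-coding genes by Fisher's exact test. The signal of a list was the median peak value of its members in the table and its percentile among 10000 random lists of the same size matched on the number of regions per gene in 5 classes. The single-library share was the share of start-site regions made of 1 interval, compared by Fisher's exact test over 30 lists with at least 3 such genes. An interval belongs to 1 library, so a region of 1 interval was called in 1 library; a region of several intervals can come from 1 or more libraries. For the 3 lists above background in this share, z scores over genes with 1 region, against random lists matched on peak value and CpG island, were summed. The sum was set against that of the 3 lists of each of 10000 random draws of all 30 lists that had the strongest excess by the one-sided exact test over all their start-site genes, the ranking that also picks the 3 observed lists. Tests were two-sided, adjusted by the Benjamini-Hochberg method within each family of lists, and called at an adjusted p of 0.05; percentiles were called outside the central 95%. Shares of lists have exact (Clopper-Pearson) 95% intervals, which cover counting over genes only. The CpG island difference used 100000 permutations and 2000 bootstrap draws. Genes and regions are not replicates, neighbours can share a region, and all p-values and percentiles describe these tables, not mice.

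The list procedures were tested on simulated data with lists of 25 of the 14469 genes. With no effect, 6% of 100 lists of medians and 4% of 200 lists of coverage were called; a planted 1.5-fold difference was called in 92% of 50 lists and a 2-fold difference in 100%. A planted coverage of 0.95 was called in 100% and of 0.2 in 98% of 50 lists, against a background of 0.6. Alternatives were windows of 500 and 5000 bp, starts inside a region, any assigned region, another background, unmatched random lists, genes with 1 region only, matching on genes per region, and matching on peak value. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.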

Results

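Binding of TFIIB, the general transcription factor that bridges TATA-binding protein and RNA polymerase II at promoters, was mapped by chromatin immunoprecipitation and sequencing in whole hearts of C57BL/6 mice. The series holds 3 ChIP libraries made with an antibody to Gtf2b, the protein also called TFIIB, and 1 library of input DNA. The ChIP libraries came from the normal adult heart at 12 weeks, from the adult heart after 4 days of transaortic coarctation (TAC), an operation that narrows the aorta and loads the left ventricle, and from the neonatal heart at 1 to 2 days, a time of normal postnatal growth. Each group has 1 library, so no value has a replicate error and no difference between conditions could be tested. The deposited tables list 20364 merged regions of TFIIB signal and 14469 genes assigned to them, in mm9 coordinates. Total reads per library are unknown from these tables. The columns of the individual libraries carry codes that match none of the sample labels, so the values described here are those the tables give over all libraries together, and TAC, adult and neonatal hearts were not compared.

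TFIIB regions in the mouse heart concentrated at the starts of genes. Of the 20364 regions, 9969 (49.0%) were centred within 1000 bp of an annotated start, and 9039 (44.4%) within 500 bp. Start-site regions were centred a median of 55 bp downstream of the start, and 38.4% of them were centred upstream of it. A further 2133 regions (10.5%) lay 1000 to 5000 bp from a start. Regions farther than 5000 bp from the start of an assigned gene numbered 5249 (25.8%), of which 3582 lay inside the gene, and 3013 regions (14.8%) were assigned to no gene. The regions covered 26.4 Mb on 21 chromosomes, with a median length of 1155 bp and an interquartile range of 786 to 1620 bp. Chromosome 11 held the most, 1729 regions, against 391 on X and 3 on Y.

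Start-site regions of the heart were mostly CpG-island promoters, the type typical of broadly expressed genes. A CpG island lay in 8358 of the 9969 start-site regions (83.8%) and in 1834 of the 10395 others (17.6%), an odds ratio of 24.2 with a 95% interval of 22.5 to 26.1. Regions made of a single called interval were less frequent at starts. A region made of 1 called interval was called in 1 library, and such regions were 19.7% of start-site regions but 67.7% of the others (odds ratio 0.117, 95% interval 0.110 to 0.125). They made up 14.5% of start-site regions with a CpG island, 46.5% of those without, 28.0% of other regions with an island and 76.2% of other regions without. Regions of 1 interval had a median length of 786 bp, against 1670 bp for the 6975 regions built from 3 or more intervals. Regions within a chromosome are not independent samples, and these intervals describe the deposited region set.

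**Figure D1:**
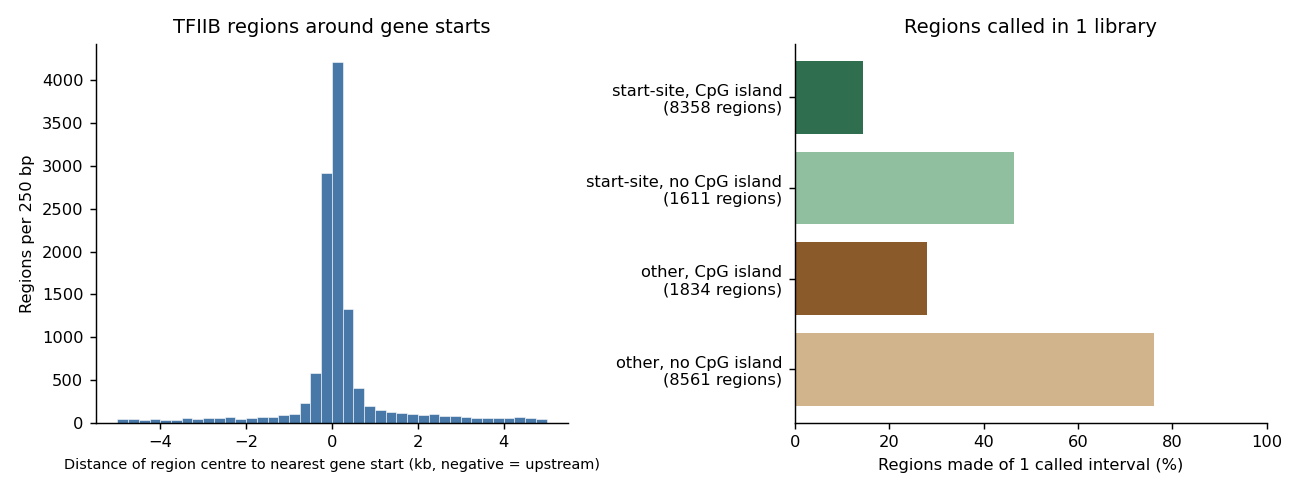
Left, number of TFIIB regions per 250 bp of distance between the region centre and the start of its nearest assigned gene, in kb, with upstream as negative. Right, percent of regions made of 1 called interval, by distance class (start-site regions are centred within 1000 bp of a start) and CpG island; the share runs from 14.5% at start-site regions with an island to 76.2% at other regions without.

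Signal followed the same division. Among start-site regions of genes with no other region, each counted a single time, the authors' highest peak value had a median of 33 over 4304 regions with a CpG island and of 20 over 643 regions without. The mean log2 difference was 0.66 (95% bootstrap interval 0.60 to 0.72) with a permutation p of 1e-05, the smallest that 100000 permutations can give. Start-site regions shared by a divergent gene pair, transcribed in opposite directions from a common promoter, numbered 889 (8.92%). They held a CpG island in 94.3% of cases against 82.8% of other start-site regions (odds ratio 3.41, Fisher's exact p = 8.54e-23). Of these 889 shared promoters, 89 were of 1 interval, against 20.7% of the other start-site regions (odds ratio 0.427, Fisher's exact p = 3.75e-16).

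Among the highest TFIIB signals were those listed for Jund1, Id3, Atf4 and Polr2a. The authors' peak value of a gene is the highest value in any library over the regions assigned to it; its scale is not stated. Its median over 14469 genes was 34, with an interquartile range of 24 to 47, a 99th percentile of 178 and a maximum of 298. That maximum belonged to Jund1 (now Jund), an AP-1 subunit, with a start-site region of 4 intervals on chromosome 8. Id3, an inhibitor of DNA binding by helix-loop-helix factors, had 281, Atf4, a central factor of the integrated stress response, had 269, and Polr2a, the largest subunit of RNA polymerase II, had 262. A peak value is given to every gene near the region, so Mknk2 and Mobkl2a both carried 281, Rps19bp1 and Smcr7l carried 269 as Atf4 did, and Amac1, next to Polr2a, carried the same 262.

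Genes with a single assigned region give a value that belongs to that region alone. Among the highest of these were Cdkn2aip at 260, the endoplasmic reticulum chaperone Hspa5 at 257, the antiproliferative gene Btg1 at 245, the small GTPase gene Rhob at 244 and the constitutive heat shock protein gene Hspa8 at 235. Arl15 had 227, Csrp2, a LIM-domain protein gene, 225, Eapp 223 and the splicing factor gene Sfrs7 (now Srsf7) 222. For Hspa5 the region spanned 34626509 to 34628972 on chromosome 2, over the start of the gene at 34627615. These genes were taken from those whose 1 region was centred within 1000 bp of the start. Genes with 1 region centred elsewhere, with values up to 231, were left out by that choice. The regions of the named genes all held a CpG island and at least 3 intervals.

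Genes known to respond to cardiac hypertrophy carried TFIIB regions at their starts; for those with several regions the peak value need not be that of the start. Nppb, encoding the B-type natriuretic peptide (chromosome 4, 147360006 to 147361307), had a peak value of 102, at the 96.5th percentile of genes, and a region of 3 intervals centred 139 bp upstream of the start, from 147359316 to 147360418. Its neighbour Nppa, encoding the atrial natriuretic peptide (chromosome 4, 147374855 to 147376176), had a peak value of 30 at the 39.3rd percentile, from 1 region of 1 interval at 147374052 to 147375226. Ankrd1, a stress-responsive muscle ankyrin repeat gene on chromosome 19, had 122, with a region of 2 intervals over its start at 36193947 to 36194953. Acta1, the skeletal actin gene on chromosome 8, had 48, with a start region of 1 interval at 126418281 to 126419130. Gtf2b, the gene of TFIIB itself (chromosome 3, 142428211 to 142446570), had 204, at the 99.5th percentile, with a region of 3 intervals and a CpG island from 142427464 to 142429144.

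The myosin heavy chain locus on chromosome 14 carried TFIIB regions along Myh6 and around both ends of Myh7. Myh6, encoding the alpha heavy chain of the adult mouse ventricle (55560761 to 55585408, minus strand), was assigned 24 regions, the most of any gene, with 18 of them inside the gene. Myh7, encoding the beta heavy chain (55589525 to 55613386, minus strand), was assigned 14. Together the pair held 30 different regions between 55556143 and 55624772, none with a CpG island, and 29 of them were made of 1 interval. The exception was a region of 4 intervals and 5314 bp, from 55584978 to 55590292, which covered the start of Myh6 and reached the end of Myh7. The start of Myh7 had a region of 1 interval from 55612686 to 55614108. Both genes carried a peak value of 95, and their shared regions prevent assigning it to either.

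Oxidative phosphorylation, proteasome, histone and ribosomal protein genes had TFIIB at nearly every start. A start-site region was present at 43 of 43 oxidative phosphorylation genes, 34 of 34 proteasome and ubiquitin genes, 29 of 29 replication-dependent histone genes and 54 of 55 genes of cytosolic ribosomal proteins, against 55.5% of 18403 named protein-coding genes. Coverage was also above that background for the TCA cycle (18 of 19), ribosome biogenesis (21 of 22), transcription machinery (37 of 39), translation factors (28 of 30), the unfolded protein response and heat shock (28 of 30) and RNA splicing (35 of 40). Over 34 gene lists, 22 lay above the background and 4 below it by Fisher's exact test, two-sided with Benjamini-Hochberg adjustment. Adjusted p-values in the groups named so far ran from 1.39e-11 for ribosomal proteins to 0.000691 for the TCA cycle.

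Hypertrophy markers had a start-site region at 22 of 23 genes (95.7%, exact 95% interval 78.1 to 99.9%; adjusted p = 8.17e-05), the exception being Cmya1 (now Xirp1). Adult sarcomere genes had it at 18 of 23 (78.3%, 56.3 to 92.5%; exact test, adjusted p = 0.0449). Csrp3, Myl2, Myh6 and Nebl were among those with no region centred within 1000 bp of the start, although Csrp3 carried a peak value of 118 and Myl2, the ventricular regulatory light chain gene, of 88 from other regions. Fatty acid oxidation (27 of 31), glycolysis (17 of 21), cell cycle (41 of 45), CDK inhibitors and growth arrest (16 of 18), immediate early genes (27 of 31), inflammatory genes (27 of 31), cytoskeleton and focal adhesion (34 of 37), extracellular matrix and fibrosis (35 of 46), chromatin and development regulators (23 of 30) and endothelial markers (19 of 21) were also above the background. With starts counted only within 500 bp, the calls for adult sarcomere (56.5%), glycolysis (61.9%), CDK inhibitors (61.1%), immediate early genes (51.6%), extracellular matrix (65.2%), cytoskeleton (67.6%) and chromatin regulators (63.3%) were lost. Each was kept with starts counted when inside a region, at 87.0%, 90.5%, 88.9%, 96.8%, 82.6%, 97.3% and 76.7% in that order. The call for chromatin regulators was also lost when any region of the gene counted (86.7%).

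Lineage genes of red cells, nerve and tissues outside the heart had few TFIIB starts. Haemoglobin and erythroid markers had a start-site region at 1 of 12 genes, Tfrc, the transferrin receptor gene (exact test, adjusted p = 0.00324). Schwann and neuronal markers had it at 2 of 14, including Tubb3 (exact test, adjusted p = 0.00367). Genes of other tissues had it at 2 of 26, Ckm and Actn3, both muscle genes (exact test, adjusted p = 2.93e-06). Adipocyte markers had it at 2 of 10 (exact test, adjusted p = 0.0382), a call lost under each of 5 alternative settings. Not past the threshold were fetal contractile isoforms (10 of 12), calcium handling and ion channels (18 of 25), cardiac transcription factors (21 of 28), growth factor signalling (25 of 37), fibroblast markers (13 of 16), smooth muscle and pericyte markers (11 of 14), macrophage and leukocyte markers (15 of 25) and epicardial markers (3 of 10). Of these, cardiac transcription factors lay above the background under 4 of 5 alternative settings, growth factor signalling and fibroblast markers under 3, fetal contractile isoforms and smooth muscle markers under 2 and calcium handling under 1. Cardiac transcription factors without a region centred at the start included Gata4, Mef2c and Mef2d. A long region centred farther away can still cover a start. Mef2d was assigned a region of 6537 bp with 5 intervals and a CpG island. With starts counted when inside a region, coverage of the list was 82.1%, above the background.

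Histone, immediate early and chaperone genes carried the highest TFIIB signal of the lists. The median peak value was 149 over 29 replication-dependent histone genes, 111 over 31 immediate early genes and 101 over 30 genes of the unfolded protein response and heat shock, against 34 over all genes. Each of these medians was above those of all 10000 random lists matched on the number of regions per gene. Immediate early genes with high values were Klf2 at 238, Junb at 219, Klf4 at 208, Fos at 179, Egr1 at 174 and Jun at 165, while Egr2 and Egr3 had 33 and 31. Among chaperones, Calr had 192, Hsp90aa1 178 and Dnaja1 165. Histone genes are near-identical copies in clusters, their 29 starts share 26 regions, and the assignment of reads among them is uncertain.

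Adult sarcomere, cytoskeletal and glycolytic genes followed. Adult sarcomere genes had a median of 79, with Tpm1 at 153, Actn2 at 141, Csrp3 at 118, Tnnt2 at 110 and Ttn, encoding titin, at 106. The cytoskeleton and focal adhesion list had 69, with Actb at 186 and Vim at 156, hypertrophy markers 67, with Ctgf at 170 and Hspb1 at 147, and glycolysis 63, with Gapdh at 190 and Aldoa at 146. Medians of 60.5 for cytosolic ribosomal proteins, 58 for CDK inhibitors and growth arrest, with Cdkn1a at 144, 55 for translation factors and 51.5 for RNA splicing were also above the central 95% of random lists. Further above it were the TCA cycle and fatty acid oxidation at 49 each, oxidative phosphorylation at 44 and chromatin regulators at 43. When only genes with 1 region at the start were used, the medians of adult sarcomere (58 over 3 genes), fatty acid oxidation (38.5 over 10), oxidative phosphorylation (39 over 21) and translation factors (41 over 19) lay inside that range. Genes of other tissues had a median of 50.5 over 6 genes, of which Prm1 and Prm2, sperm protamine genes, took their 65 from a region away from their starts; against unmatched random lists this call was lost.

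Smooth muscle and pericyte markers (median 20.5 over 14 genes), macrophage and leukocyte markers (22.5 over 20) and adipocyte markers (18.5 over 6) had lower TFIIB signal than matched random lists. Those random lists were matched on regions per gene, not on CpG island. Start-site regions of genes with no other region had a median of 20 without an island and 33 with one. Whether islands account for these low medians was not tested. Myh11, the smooth muscle myosin gene, had 13, Tagln 16 and Rgs5 17, while Smtn had 132. Cell cycle genes had a median of 30, at the 5.84th percentile, and 24 over 21 genes with 1 region at the start, at the 1.7th percentile and below the central range. Inside the central range were the lists of transcription machinery (38), proteasome (35), ribosome biogenesis (36), cardiac transcription factors (42), calcium handling (38), fetal contractile isoforms (35), growth factor signalling (34), extracellular matrix (37), inflammatory genes (42), endothelial (34), fibroblast (43.5), epicardial (22.5), erythroid (23) and neuronal markers (26.5). In those lists single genes stood high, among them Actc1, the cardiac actin gene, at 207, Atp2a2, the sarcoplasmic calcium pump gene, at 136, Tbx20 at 135 and Flt1 at 133. Over 34 lists, 1.7 are expected outside the central range by chance, and 19 lay outside it. The 19 include genes of other tissues, the list planned as background, which lay above the range at the 97.84th percentile.

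Cell cycle, fetal contractile and macrophage genes had start-site regions called in 1 library more often than other genes. Such regions were found at 17.7% of the 10216 named genes with a start-site region. They were found at 11 of 15 macrophage and leukocyte genes (73.3%, exact 95% interval 44.9 to 92.2%; Fisher's exact test, adjusted p = 0.000107), among them Csf1r, the receptor that controls macrophage survival, Cd14, Cd68, Ptprc and Cx3cr1. They were found at 6 of 10 fetal contractile genes (60%, 26.2 to 87.8%; exact test, adjusted p = 0.0259), namely Myh7, Acta1, Tnnt1, Tnni1, Myl9 and Tagln, of which Tagln is also in the smooth muscle list. Of the cell cycle genes, 15 of 41 had them (36.6%, 22.1 to 53.1%; exact test, adjusted p = 0.0259), including the mitotic kinase genes Aurkb, Bub1 and Plk1, the replication helicase genes Mcm3 and Mcm6, Top2a, Ccnb1 and E2f1. Which library held each region was not used here, and in the 29 of these genes with 1 region, matched on peak value and CpG island, the excess lay at the 97.08th percentile of lists picked in the same way from random draws, inside the central 95%. The fetal contractile call was lost with starts within 500 bp and with starts required inside a region (5 of 9 genes; exact test, adjusted p = 0.0603 for the latter).

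Ribosomal protein genes showed the opposite, with 1 of 54 start-site regions (1.85%) made of 1 interval (exact test, adjusted p = 0.00781), that of Rpl4. None of 28 genes of the unfolded protein response and heat shock and none of 18 TCA cycle genes had such a region, with adjusted p of 0.0605 and 0.174. The other lists also did not pass the threshold, among them adult sarcomere (1 of 18, Myom2), oxidative phosphorylation (2 of 43), cardiac transcription factors (1 of 21, Tbx5), hypertrophy markers (4 of 22), endothelial markers (6 of 19) and growth factor signalling (7 of 25). In all, 30 lists with at least 3 start-site genes were tested. Whether a weak region passes the authors' calling threshold depends on library depth, which is unknown. Against random lists matched on the gene's highest peak value, which need not be that of its start-site region, the ribosomal protein call was lost and the other 3 were held, and replication-dependent histones (5 of 29, 17.2%) then lay above the range.

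**Figure D2:**
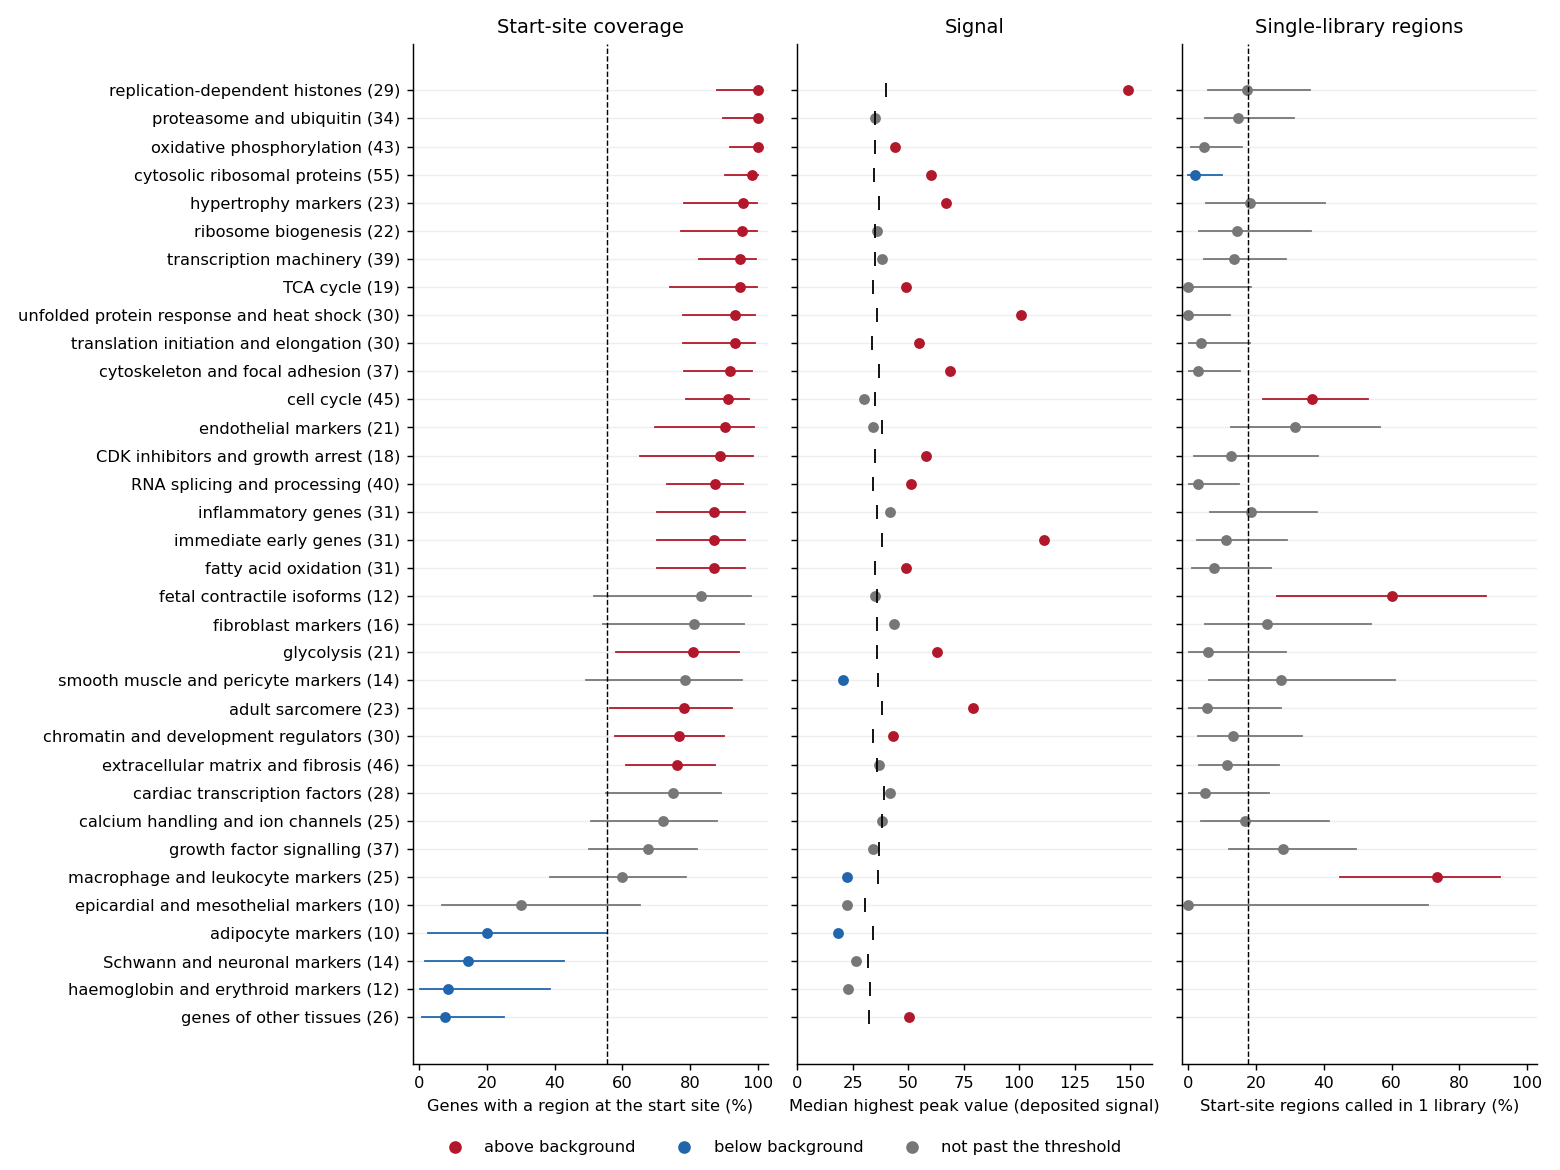
For 34 gene lists (members in parentheses), percent of genes with a TFIIB region at the start (left), median of the authors' highest peak value (middle) and percent of start-site regions called in 1 library (right). Horizontal lines are exact 95% binomial intervals, dashed lines the background of 55.5% and 17.7%, short black bars the median of matched random lists, and red and blue mark lists above and below background; lists with under 3 start-site genes have no point on the right.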

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

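The windows of 500 and 5000 bp for the location of regions were planned; all other alternatives in this part were chosen after seeing the data. No paired analysis was possible because each group has 1 library and the library columns were not assigned to groups. For the same reason the settings planned for the comparisons of TAC, adult and neonate (pseudocount, filter, scaling, input subtraction, average signal, gene summary, fold threshold and presence calls) were not run, and no library was left out, since the library columns were not used.

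Region location, CpG island share and signal, the single-library share, and the numbers of lists called for coverage, for signal and for more single-library regions stayed on their side of the threshold or within 1.5 times of the reported count in 30 recomputed values. The number of lists above the coverage background was 22 and ranged from 16 with a 500 bp window to 28 against all protein-coding genes. The number of lists with fewer single-library start-site regions than background was 1 as reported, 5 with starts within 5000 bp and 0 when matched on peak value; the cause was not tested. Of values for single lists with a call in at least 1 setting, 178 kept the reported call, 21 lost it, 22 gained a call, 31 stayed uncalled as reported, and none changed direction. Coverage calls were gained by cardiac transcription factors under 4 of 5 settings (75% to 89.3%), by growth factor signalling and fibroblast markers under 3, by fetal contractile isoforms and smooth muscle markers under 2 and by calcium handling under 1; adipocyte markers lost theirs under all 5. Sequencing depth is unknown and limits what regions of 1 interval show, since a deeper library can yield more weak regions.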

Other observations

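All tests in this part were chosen after the tables had been seen; of the 7 tests of explanations, the first on single-library regions was also written after its result was seen, and the last on them after the values it rests on were seen.

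TFIIB regions inside genes, farther along the gene body than the start, were frequent in several gene lists. Of the 14469 genes, 1058 (7.31%) had 2 or more such inner regions. They occurred at 9 of 21 endothelial markers, led by Pecam1 with 6, at the 100th percentile of random lists matched on gene length, and at 8 of 37 cytoskeletal genes, led by Pxn, encoding paxillin, with 11 and the nonmuscle myosin gene Myh9 with 8 (99.9th percentile). Cardiac transcription factors had them at 9 of 25 genes, including Nfatc1 and Prdm16 with 5 each, and calcium handling genes at 8 of 21, including Jph2 with 8 and the potassium channel gene Kcnq1 with 7 (99.8th and 99.6th percentile). Hypertrophy markers had them at 5 of 23 genes (99.2nd percentile), growth factor signalling genes at 7 of 29 (99.1st) and fetal contractile isoforms at 2 of 11 (97.9th). No oxidative phosphorylation, TCA cycle, ribosomal protein, translation or proteasome gene had 2 or more, and this was inside the range of random lists. Smooth muscle and pericyte markers, at 3 of 14 genes (92.2nd percentile), were also inside that range. Over all genes, Tns1, encoding tensin, held the most, 21. In the 34 lists these shares were not adjusted for the number of lists.

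The longest TFIIB region spanned 11370 bp on chromosome 5, from 143574594 to 143585964, with 13 intervals and the single gene Zfp469 (now Tnrc18). A region of 10563 bp and 10 intervals on chromosome 19 was assigned to 2310043N10Rik (now Neat1, a nuclear long noncoding RNA gene) and 1200004M23Rik (now Frmd8). On chromosome 8, a region of 7637 bp from 86721018 to 86728655 was assigned to the microRNA genes Mirn23a, Mirn27a and Mirn24-2, which lie beyond its end, from 86732416, and to Zswim4. The transcription factor gene Hes1, a Notch target, had a region of 6609 bp with 8 intervals.

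Adult sarcomere genes had 2 or more inner regions in 34.8% of 23 genes, among them Myh6 with 18, Tnnt2 with 8 and Ldb3 with 6, against 8.70% in random lists. Longer genes alone do not account for this, since the share lay at the 99.99th percentile of lists matched on length. Nor do deposited starts of other genes or CpG islands inside the genes, since without such regions the share lay at the 100th percentile. Only the deposited start of each gene was used. This test thus cannot decide on further starts of the same gene, which stay open. The length-matched comparison repeats the one made for all 34 lists, and neither percentile is adjusted for the choice of this list. A hypothesis is that factor or polymerase complexes crosslinked along heavily transcribed genes may give these regions. It was not tested, since transcription was not measured. Shares above random lists also occurred at endothelial markers (42.9%, median peak value 34) and cytoskeletal genes (21.6%, median 69). The excess was thus not confined to lists of high signal. Of the 24 regions assigned to Myh6, 23 were made of a single interval, hence called in a single library. Library depth, which is unknown, therefore also stays open. Open chromatin recovered in any ChIP, which the input library could show, stays open because its values were not used here. No biological difference between the hearts was tested.

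Start-site regions called in 1 library were frequent at cell cycle, fetal contractile and macrophage genes, 48.5% of 66 genes against 24.2% in random lists matched on the gene's highest peak value (100th percentile), but that value need not belong to the start-site region and decides nothing on weak regions. Among the 29 genes with 1 region, whose value is the region's own, the share was 51.7% against 31.0% with matching also on a CpG island, at the 99.68th percentile; 21 of them were cell cycle genes (z of 2.40), with 4 macrophage (1.32) and 4 fetal contractile genes (0.80), while hypertrophy markers (2.74) and proteasome genes (1.44) were not among the picked lists. These 3 lists had been picked by the exact test over 30 lists; when 3 lists were picked by that test in each random draw, their summed z over those genes, 4.52 against a median of 1.34, lay at the 97.08th percentile, just inside the central 95%. Weak regions that pass the calling threshold in 1 library, together with this choice of lists, therefore stay open as an explanation, as do library depth, tissue handling and, untested because the library of each region was not used here, binding in 1 of the 3 groups.

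Immediate early genes had a median peak value of 111 among all 31, and also among the 27 with a start-site region, against 39 in random lists matched on regions per gene and CpG island, at the 100th percentile. The highest of several regions does not account for it, since 7 of these genes with 1 region at the start had a median of 130 against 32, also at the 100th percentile. The histone genes, examined before the single-library regions were taken up in their place, were also matched on the number of genes per start-site region. Their median of 149 stayed above the random lists. This cannot decide on signal taken from a neighbour's region, since the value is the highest over all regions assigned to a gene. Only 3 histone genes had 1 region, at the start, with a median of 170 against 32 in random lists. Stress during removal and handling of the hearts could raise immediate early genes in every library, and that was not tested, nor was any difference between TAC, adult and neonate.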
